A study of Homo sapiens with 26 samples.

How the data were processed

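RNA sequencing had been done on H9 cells (WA09), an established human embryonic stem cell line, which per the labels' protocols had been irradiated with X-rays from 1 tube of a computed tomography scanner, left to recover and then directed to neural lineages through embryoid bodies. The 26 libraries fell into 9 groups by day (0, 6 and 10) and dose (0, 15 and 500 mGy), taken with the replicate numbers from the labels. Each group had 3 libraries except day 6 at 15 mGy, which had 2 (replicates 1 and 3). The labels call the replicates biological without saying what a shared number stands for. RNA had been purified with a column kit and libraries made with a NEBNext kit, per the labels' protocols. Whether the counting used strand is not given in the sources used here, so reads of overlapping and antisense genes may be shared.

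The authors deposited 1 table of FPKM (fragments or reads scaled by gene length and by assigned reads) for 48162 genes in 26 columns, 1 per library, with gene names and positions. The submitters' processing notes name CASAVA, STAR and HTSeq, without versions, and the genome build hg19. The annotation release and any read filter are not given in the sources used here. The deposited gene length, given per the file headers in bp, multiplied by FPKM summed to the same total in every library. It gave whole reads, within 0.02 read, for 100% of the 611249 values above 0. The depth recovered this way ran from 6034935 assigned reads (day 0, 15 mGy, replicate 2) to 26448402 (day 0, 0 mGy, replicate 2). The day 0, 15 mGy, replicate 2 library is therefore the least precise for genes of low level. Because the deposited unit was FPKM, these reads served only as an added alternative.

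All tests ran on log2(FPKM + 1), so a log2 change understates the change of a gene of low level. Genes at an FPKM of 1 or more in at least 2 libraries were kept, which left 16840. The main test was limma (version 3.58.1, in R 4.3.3) with a mean-variance trend, 1 fit of 9 group means over 26 libraries, and Benjamini-Hochberg adjustment per comparison with a threshold of 0.05. There were 16 comparisons. Unirradiated cells were compared between days, doses were compared within each day, and the response to each dose was compared between days as an interaction. Every adjusted p of a single gene below comes from limma, and every adjusted p of a gene list from camera. SE stands for the standard error of the fitted log2 change, and SD for the spread of FPKM between libraries. The SE pools a gene's spread over all 26 libraries. For a gene near 0 FPKM at other days it can understate the spread at the day compared.

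Genes were named by a rule set before the data were examined. For each comparison of days, or of a dose with 0 mGy, it took the 10 genes that rose most and the 10 that fell most among those past the threshold whose groups did not overlap, leaving out clone names and pseudogenes. Where none passed it took the 3 with the smallest p per direction. It added up to 4 members of each gene list, CDKN1A, MDM2, GDF15, BAX and FDXR for irradiation, and POU5F1, NANOG, PAX6, SOX1 and NES for days. Not every gene that the rule takes is reported here. The 25 gene lists were also set before the data were examined, and 23 had at least 5 measured members. Those 23 were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the residuals.

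The replicate number was checked as a pairing by correlating the deviations of same-numbered libraries from their group means. In 8 of 12 pairwise comparisons there were 3 pairs and every correlation was over 0.1. There the numbers are treated as pairing the libraries. The exceptions were 15 minus 0 mGy at day 0, day 10 minus day 0 and both comparisons with day 6 at 15 mGy, which had 2 pairs. This check cannot show that replicates 2 and 3 pair by number. Both lie away from replicate 1, which alone gives them like deviations, and libraries of unlike number were not correlated. For 500 minus 0 mGy at day 10 the correlations of replicates 1, 2 and 3 were 0.39, 0.11 and 0.15. A fit with the replicate number as a block was also run (within each day for doses, over all libraries for days). Where the numbers are treated as pairing, it is given beside the main value if it changes a call or moves a count by over 1.5 times. Between libraries of 1 group, the chi-square of the recovered reads per degree of freedom was at least 4.68 in all 25 pairs. No 2 libraries therefore differed by read sampling alone. This cannot show that 2 libraries came from separate cultures. The closest pair was day 0, 500 mGy, replicates 2 and 3, and the next lowest value was 18.89 (day 10, 15 mGy, replicates 2 and 3).

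Both fits were tested on simulated data for 500 minus 0 mGy at day 10, in 20 simulations of 16840 genes with 100 genes changed 2-fold and 100 changed 4-fold in each. Without the block, 12.2% of the 2-fold and 77.5% of the 4-fold changes were recovered, and 1.32% of all calls were false. With the block, 61.4% and 94.1% were recovered, and 10.99% of all calls were false, above the 5% that the threshold aims at. The simulated libraries were built from the blocked fit, with the same replicate differences at each dose of a day. The pairing was thus assumed, and these values need not hold for the real libraries if the numbers do not pair them. The blocked counts of the other comparisons were not simulated. The alternatives were another pseudocount (0.1), no filter, median-ratio scaling, fits of fewer libraries, the block, a least log2 change of 1 and leaving out each replicate. Fits of replicates 2 and 3 alone, and limma voom on the recovered reads with and without the block, were added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Gene positions are those of the deposited table, on hg19.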

Results

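Gene expression was measured by RNA sequencing in H9 human embryonic stem cells exposed to 0, 15 or 500 mGy of X-rays and followed through neural differentiation. Libraries were made from pluripotent cells (day 0), embryoid bodies (day 6) and neural rosettes (day 10), with n = 3 libraries per group and n = 2 at day 6 after 15 mGy. Assigned reads per library ranged from 6034935 to 26448402. The stage of the cells accounted for most of the variation. Principal component 1 (55.4% of the variance) separated day 0 from days 6 and 10.

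Principal component 2 (13.6%) separated the replicate 1 libraries from replicates 2 and 3 at every day and dose. RNA of the 13 mitochondrially encoded genes took 23.3% to 39.7% of the assigned reads in the 3 replicate 1 libraries of day 0, and 2.38% to 5.72% in the other 6. At day 6 the shares were 8.37% to 12.05% against 3.36% to 6.14%, and at day 10 they were 10.7% to 10.9% against 2.84% to 6.53%. FPKM is relative to all assigned reads. The median-ratio factor, which is low where the typical gene of a library is low, was 0.675, 0.842 and 0.848 in the replicate 1 libraries of day 0 and 0.951 to 1.03 in the other 6, while at days 6 and 10 the ranges of replicate 1 and the other replicates overlapped.

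**Figure D1:**
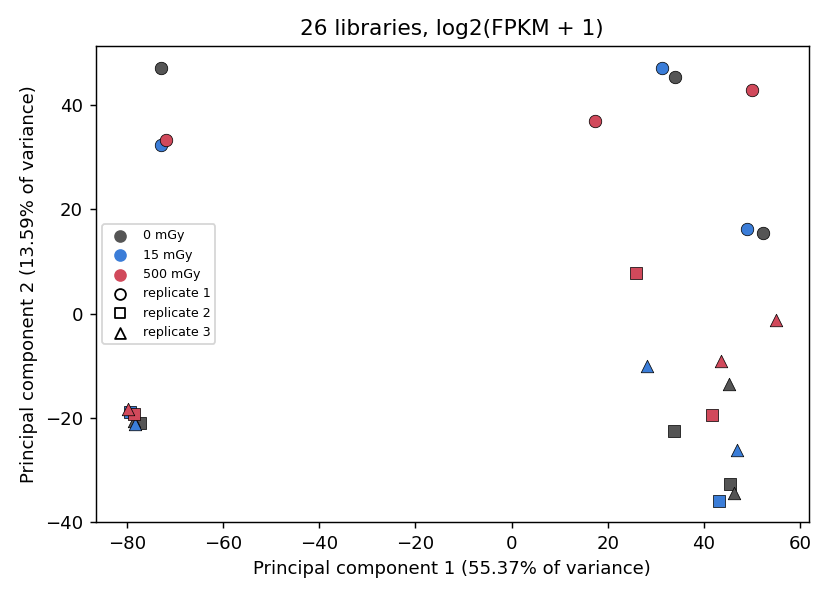
Each point is 1 of the 26 libraries on principal components 1 (55.4% of the variance) and 2 (13.6%) of log2(FPKM + 1), coloured by dose in mGy and shaped by replicate number. Day 0 lies at the left, days 6 and 10 at the right, and the replicate 1 libraries lie above the others.

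**Figure D2:**
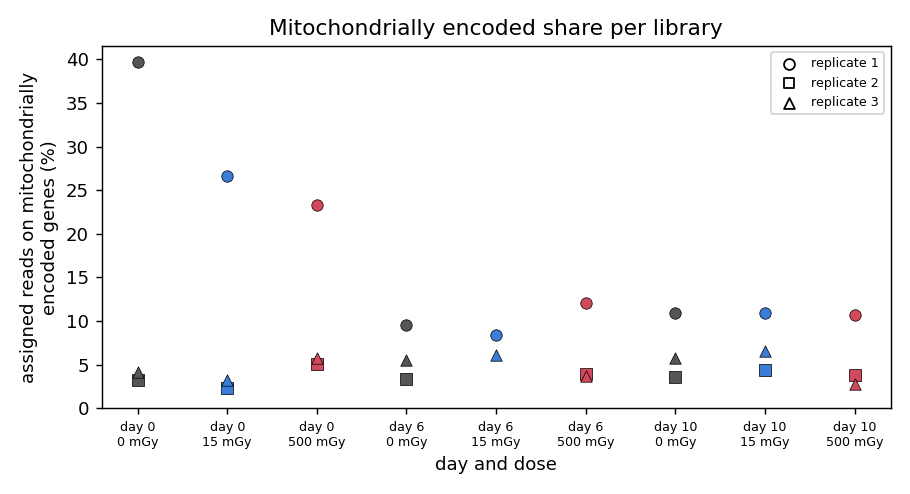
Share of assigned reads on the 13 mitochondrially encoded genes, in percent, for each library by day and dose, with shapes for replicate numbers. The replicate 1 libraries of day 0 reached 23.3% to 39.7%.

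The comparison of unirradiated cells between days asked which genes changed as pluripotent cells took on a neural identity. By day 6 the pluripotency genes had fallen steeply. POU5F1 (ENSG00000204531, hg19 chromosome 6, 31130253 to 31148508), a core transcription factor of pluripotent cells, went from 394.8 ± 270.0 FPKM (SD, n = 3) to 0.684 ± 0.681 (SD, n = 3), a log2 change of -7.63 (SE 0.47, limma adjusted p = 3.61e-11). Its processed copies elsewhere in the genome can share its reads. NANOG went from 22.3 ± 10.8 FPKM (SD, n = 3) to a listed value of 0 in all 3 libraries. TDGF1, a co-receptor of NODAL signalling, changed by -6.77 (SE 0.24), and the transcription factor PRDM14 by -5.43 (SE 0.29). The epithelial adhesion genes CDH1 and EPCAM changed by -5.63 (SE 0.22) and -5.43 (SE 0.36). Of the 20 pluripotency genes, 15 fell and 5 did not pass (17 fell when adjusted over the list alone), and the list shifted down (camera adjusted p = 1.52e-21, and 0.000397 with an estimated correlation).

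Neural progenitor genes rose over the same interval. PAX6 (ENSG00000007372, hg19 chromosome 11, 31806340 to 31839509), a regulator of neuroectoderm and eye development, rose from 0.197 ± 0.0806 FPKM (SD, n = 3) to 61.6 ± 27.9 (SD, n = 3), a log2 change of 5.59 (SE 0.41, limma adjusted p = 6.83e-10). The forebrain and eye-field gene RAX rose by 6.17 (SE 0.49), the NOTCH effector HES5 by 6.01 (SE 0.65), the nuclear receptor gene NR2F1 by 5.88 (SE 0.59) and DLK1 by 8.83 (SE 0.97). SOX1 rose by 3.11 (SE 0.83) and NES, which encodes the intermediate filament nestin, by 2.35 (SE 0.36). Of 27 neural progenitor genes 25 rose, 26 when adjusted over the list alone, and none fell (camera adjusted p = 1.85e-16, and 0.000501 with an estimated correlation). Among 21 neuronal genes 10 rose, including the NOTCH ligand gene DLL1 by 4.90 (SE 0.44) and STMN4 by 2.98 (SE 0.28), with adjusted p = 0.00888 for the list and adjusted p = 0.685 with an estimated correlation. Neural crest genes shifted up (adjusted p = 0.0459, and 0.809 with an estimated correlation), a call lost with the replicate block (adjusted p = 0.097). In that list SOX10 rose by 3.00 (SE 0.77), while FOXD3, which pluripotent cells also express, changed by -2.46 (SE 0.59). Genes of unfolded protein and amino acid stress shifted down (adjusted p = 0.0066, and 0.685 with an estimated correlation), among them the amino acid transporter gene SLC7A5 by -3.54 (SE 0.61) and CHAC1 by -3.21 (SE 0.44). The oxidative stress list also shifted down (adjusted p = 0.0303, and 0.809 with an estimated correlation), with HMOX1, which encodes heme oxygenase, at -2.43 (SE 0.52). Ribosomal protein genes shifted up (adjusted p = 0.00183, and 0.809 with an estimated correlation).

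Over all genes, 3333 rose and 1892 fell from day 0 to day 6. The median change of all genes was 0.207 on the log2 scale, and with median-ratio scaling it was 0.018 and the split was 2419 up and 2855 down. The ratio of rising to falling genes therefore depended on the scaling, and changes of this size in single genes are relative to that shift.

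**Figure D3:**
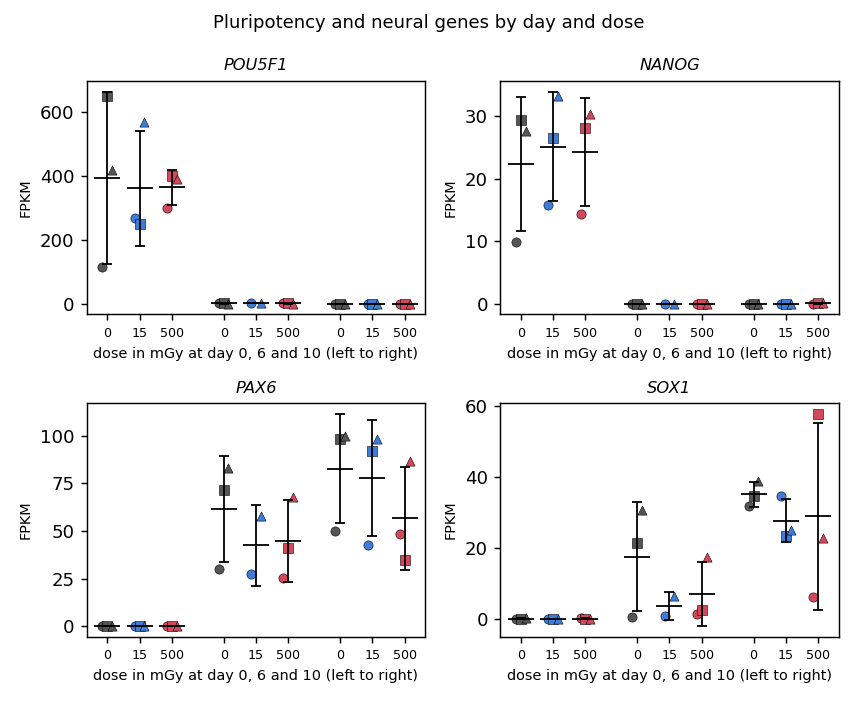
FPKM of 2 pluripotency genes (POU5F1, NANOG) and 2 neural genes (PAX6, SOX1) by dose at days 0, 6 and 10, with a point per library, shapes for replicate numbers, and bars for the mean and SD. In unirradiated cells POU5F1 went from 394.8 FPKM at day 0 to 0.684 at day 6, and PAX6 from 0.197 to 61.6.

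Between day 0 and day 10 POU5F1 changed by -8.23 (SE 0.47) and NANOG was again listed at 0 in all 3 libraries. L1TD1 and ZFP42, both expressed in pluripotent cells, changed by -6.20 (SE 0.92) and -5.74 (SE 0.50). PAX6 rose by 6.06 (SE 0.41), SOX1 by 4.87 (SE 0.83), NES by 2.27 (SE 0.36) and NR2F1 by 6.58 (SE 0.59). The forebrain transcription factor genes EMX2 and FEZF2 rose by 5.57 (SE 0.67) and 5.4 (SE 0.76), and the collagen gene COL2A1 by 5.18 (SE 0.54). The pluripotency list shifted down and the neural progenitor list up (camera adjusted p = 4.86e-23 and 1.73e-13, and 0.000265 and 0.00151 with an estimated correlation). Neuronal genes shifted up (adjusted p = 6.89e-05, and 0.349 with an estimated correlation), as did WNT targets (adjusted p = 0.0312, and 0.784 with an estimated correlation). The oxidative stress list and the unfolded protein and amino acid stress list shifted down (adjusted p = 0.0312 for each, and 0.801 and 0.784 with an estimated correlation). Of 12 genes of extracellular matrix and mesenchyme, 10 rose and 1 fell, with COL3A1 up by 4.31 (SE 0.27), and the list shifted up (adjusted p = 0.00194, and 0.253 with an estimated correlation). Of the 16840 genes 4309 rose and 1798 fell in limma. With median-ratio scaling 3003 rose and 3012 fell, and the median change of all genes went from 0.253 to 0.013.

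From day 6 to day 10 fewer genes changed, and nearly all rose. BHMT, an enzyme of betaine metabolism, rose by 4.48 (SE 0.73), the fibrillar collagen genes COL3A1 and COL1A1 by 3.93 (SE 0.27) and 3.13 (SE 0.37), BMP4 by 3.50 (SE 0.69), the retinoic acid-synthesising enzyme gene ALDH1A1 by 3.27 (SE 0.66) and ANXA1 by 3.16 (SE 0.52). The genes that fell included HES3 (-3.45, SE 0.87), PAMR1 (-3.36, SE 0.59), the POU factor gene POU3F1 (-2.47, SE 0.32), BST2 (-2.18, SE 0.52) and PAPLN (-1.90, SE 0.30). POU5F1, PAX6, SOX1 and NES changed by -0.60, 0.48, 1.76 and -0.07 and did not pass (limma adjusted p of 0.51 or more), and NANOG was listed at 0 at both days. The extracellular matrix and mesenchyme list shifted up (camera adjusted p = 7e-11, and 0.007 with an estimated correlation), with 3 of 12 members past the threshold. BMP and TGF-beta targets, neuronal genes and mesoderm genes shifted up (adjusted p = 2.34e-06, 0.000204 and 0.00296, and 0.116, 0.362 and 0.116 with an estimated correlation). Ribosomal protein, pluripotency, replication-dependent histone and DNA replication genes shifted down (adjusted p = 6.27e-08, 0.000426, 0.00856 and 0.0188, and 0.538, 0.182, 0.538 and 0.778 with an estimated correlation). In all, 223 genes rose and 19 fell. With the replicate block 494 rose and 54 fell, and the 242 genes became 49 or 126 without day 6, 0 mGy, replicate 1 or 2, and 111 or 77 without day 10, 0 mGy, replicate 2 or 3. With median-ratio scaling 161 rose and 27 fell, and in a fit of the unirradiated libraries alone 78 rose and 7 fell.

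The next comparisons asked how cells exposed to X-rays differed from unirradiated cells of the same day. In pluripotent cells at day 0, 500 mGy came with higher levels of p53 target genes. Of 33 measured p53 targets 31 had a positive log2 change, with a median of 0.48, and the list shifted up (camera adjusted p = 4.06e-22, and 0.0209 with an estimated correlation). None of the 33 passed over all genes in limma without the block, and 10 passed upward when adjusted over the list alone. With the replicate block 3 passed. These were CDKN1A, a cyclin-dependent kinase inhibitor (1.66, SE 0.23, adjusted p = 0.021), the ribosomal protein-like gene RPS27L (1.40, SE 0.24, adjusted p = 0.0391) and FDXR, a mitochondrial ferredoxin reductase (0.95, SE 0.13, adjusted p = 0.021). CDKN1A (ENSG00000124762) was at 16.7 ± 9.0 FPKM (SD, n = 3) after 500 mGy and 4.40 ± 2.45 (SD, n = 3) without irradiation, and the 2 groups overlapped. The values of GDF15 and BTG2 were 1.09 (SE 0.30) and 1.37 (SE 0.30), and those of MDM2 and BAX were 0.28 (SE 0.38) and 0.30 (SE 0.36), none past the threshold.

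The 1 gene called without the block at day 0 was MT1H, a metallothionein, which rose from 3.50 ± 1.43 to 21.5 ± 17.3 FPKM (SD, n = 3), a log2 change of 2.11 (SE 0.33, limma adjusted p = 0.026). Metallothionein genes are close copies, so its reads are uncertain. The MT1H call was lost with a pseudocount of 0.1, median-ratio scaling, the libraries of day 0 only, replicates 2 and 3 only and limma voom, and without 0 mGy replicate 1 or 3. With the block 10 genes rose and 3 fell, including EPS8L2 (1.18, SE 0.18), FOSL1 (1.44, SE 0.24) and the noncoding LINC00458 (-1.26, SE 0.19). Unfolded protein and amino acid stress genes shifted down (camera adjusted p = 7.49e-08, and 0.187 with an estimated correlation), with values of -1.76 (SE 0.43) for DDIT4 and -1.55 (SE 0.44) for CHAC1, neither past the threshold. Extracellular matrix and pluripotency genes shifted up (adjusted p = 0.00104 and 0.00479, and 0.187 and 0.355 with an estimated correlation). Without the block the count was 8 without day 0, 500 mGy, replicate 1, and 2, 2 and 0 without day 0, 0 mGy, replicates 1, 2 and 3. With the block it was 1, 17 and 0 without those 3 unirradiated libraries, and 19, 2 and 0 without 500 mGy replicates 1, 2 and 3. The balance with the block turned to 6 up and 13 down without 500 mGy replicate 1, and the 1 gene called without 0 mGy replicate 1, which was not among the 13, fell. In replicates 2 and 3 only, 1 gene rose and 5 fell without the block, and with the block none of the 13 genes nor any other passed.

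**Figure D4:**
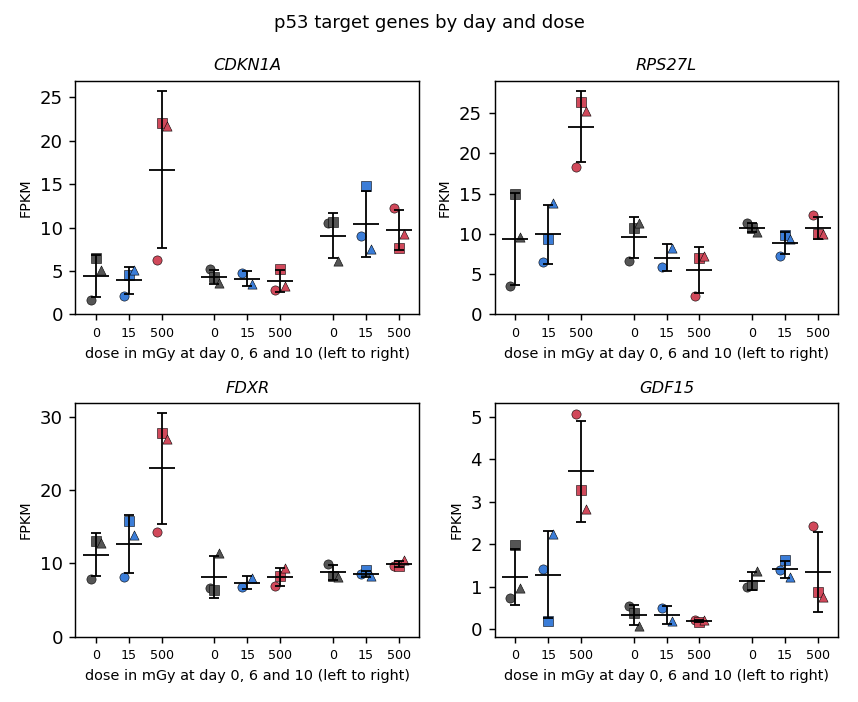
FPKM of 4 p53 target genes by dose at days 0, 6 and 10, with a point per library, shapes for replicate numbers, and bars for the mean and SD. At day 0 CDKN1A had a mean of 16.7 FPKM after 500 mGy and 4.40 FPKM at 0 mGy.

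After 15 mGy at day 0 no gene passed in limma, and 86 had an unadjusted p under 0.05. Without day 0, 0 mGy, replicate 1, 1 gene passed. CDKN1A, MDM2, GDF15, BAX and FDXR had log2 changes of -0.07, 0.20, -0.04, 0.06 and 0.14. Leaving out clone names and pseudogenes, the smallest p values upward and downward belonged to DKKL1 (0.61, SE 0.23) and RPP38 (-0.62, SE 0.27). The clone RP11-44K6.2, named after its values were seen, had the smallest adjusted p of all genes (1.26, limma adjusted p = 0.426). Limma voom called 0. Of 23 lists, the mitochondrially encoded genes alone shifted (down, camera adjusted p = 9.81e-05, and 0.986 with an estimated correlation). Without day 0, 0 mGy, replicate 1, the library with the highest mitochondrial share, the direction reversed and the list passed upward (camera adjusted p = 0.000753). Between the doses at day 0, p53 targets were higher at 500 than at 15 mGy (camera adjusted p = 2.46e-21, and 0.0245 with an estimated correlation). The 2 genes called between the doses were GLIPR1L1 (1.58, SE 0.25) and the clone CTD-2501M5.1 (-1.64, SE 0.27), both named after their values were seen. With the block 7 genes passed, and 1 of these was also called without it. The blocked count was 0 without any 1 of 15 mGy replicates 1, 2 and 3 or 500 mGy replicate 3, 1 without 500 mGy replicate 2, 24 without 500 mGy replicate 1 and 0 in replicates 2 and 3 only. Both calls made without the block were lost with a pseudocount of 0.1, the libraries of day 0 only and limma voom. Without the block the count was 11, 1 and 0 without 500 mGy replicates 1, 2 and 3, and 0 without 15 mGy replicate 3.

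In embryoid bodies at day 6 no gene passed the threshold at either dose, nor at 500 mGy with the block, and limma voom without the block called 0. At 500 mGy 851 genes had an unadjusted p under 0.05, and at 15 mGy 131 had. All 6 measured NOTCH targets had negative log2 changes at 500 mGy (median -1.0), and the list shifted down (camera adjusted p = 1.19e-07, and 0.000588 with an estimated correlation). With the block the estimated correlation gave adjusted p = 0.0809. Its members were led by HES4 at -2.57 (SE 0.64), HEYL at -1.40 (SE 0.35), NRARP at -1.03 (SE 0.32) and HEY2 at -0.77 (SE 0.29). Over all genes none of these passed, and 5 of the 6 passed when adjusted over the list alone. HES4 was at 13.1 ± 10.4 FPKM (SD, n = 3) after 500 mGy and 69.8 ± 8.34 (SD, n = 3) at 0 mGy. NOTCH targets were also lower at 500 than at 15 mGy (camera adjusted p = 8.17e-05, and 0.00759 with an estimated correlation). The 15 mGy group lacks replicate 2, and with the block 0 lists passed in this comparison with an estimated correlation.

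Neural crest and neuronal genes shifted down at 500 mGy at day 6 (camera adjusted p = 1.07e-12 and 1.19e-07, and 0.11 and 0.118 with an estimated correlation), with values of -2.89 (SE 0.77) for SOX10 and -2.04 (SE 0.48) for TFAP2A, neither past the threshold. Immediate early, hypoxia and glycolysis, WNT target and ribosomal protein genes shifted down (adjusted p = 5.3e-08, 0.00509, 0.00349 and 0.000105, and 0.11, 0.452, 0.452 and 0.568 with an estimated correlation). DNA double-strand break repair genes shifted up (adjusted p = 8.82e-05, and 0.416 with an estimated correlation). With the block alone, pluripotency and mitosis genes also passed upward and neural progenitor genes and BMP and TGF-beta targets downward (adjusted p = 0.0195, 0.0156, 0.044 and 0.0471, and 0.387, 0.488, 0.387 and 0.387 with an estimated correlation). The values of TAGLN3 and the cystine transporter gene SLC7A11 were -1.30 (SE 0.27) and 1.21 (SE 0.25). The p53 targets CDKN1A, MDM2, GDF15, BAX and FDXR were at -0.17, 0.39, -0.13, -0.45 and 0.03. Without day 6, 0 mGy, replicate 1 the count of genes at 500 mGy was 30, and without day 6, 500 mGy, replicate 3 it was 6. With the block these counts were 24 (4 up and 20 down) and 25 (11 up and 14 down), and with replicate 1 left out of every group 1 gene passed, downward.

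After 15 mGy at day 6, where 1 group had 2 libraries, neural crest and neuronal genes also shifted down (camera adjusted p = 4.74e-15 and 5.38e-09, and 0.0908 for each with an estimated correlation). Replicate 2 is missing at 15 mGy, so replicate 1 weighs more there than at 0 mGy, and its difference from the others enters this comparison. SOX1 was at 0.677 FPKM in day 6, 0 mGy, replicate 1 and at 21.6 and 30.7 in replicates 2 and 3. With the block 12 of 23 lists passed at the preset correlation, and 0 with an estimated one. NOTCH targets, WNT targets, immediate early genes and extracellular matrix genes shifted down (adjusted p = 0.0111, 0.000409, 0.0228 and 0.0125, and 0.0908, 0.328, 0.655 and 0.328 with an estimated correlation). The direction of the immediate early list reversed without day 6, 15 mGy, replicate 3 (adjusted p = 0.271). Pluripotency, mitosis and DNA double-strand break repair genes shifted up (adjusted p = 0.00351, 0.0223 and 0.0223, and 0.322, 0.655 and 0.655 with an estimated correlation). The values of DACT3 and LRRN3 were -0.89 (SE 0.24) and 0.89 (SE 0.32), and the 5 p53 targets lay between -0.19 and 0.02.

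In neural rosettes at day 10, 2 genes passed at 500 mGy without the block. PAPLN (ENSG00000100767), which encodes an extracellular matrix glycoprotein, was at 7.86 ± 3.79 FPKM (SD, n = 3) against 1.21 ± 0.719 (SD, n = 3), a log2 change of 1.97 (SE 0.30, limma adjusted p = 0.0108). COL3A1 (ENSG00000168542) was at 3.86 ± 1.40 FPKM (SD, n = 3) against 21.2 ± 7.94 (SD, n = 3), a log2 change of -2.16 (SE 0.27, limma adjusted p = 0.000661). Neither call was made when the libraries of day 10 were fitted alone. COL3A1 was at 0.7845 FPKM or less in every library of days 0 and 6, where log2(FPKM + 1) varies little. Its SE pools those libraries, so its adjusted p does not measure the spread at day 10 alone. The COL3A1 call was also lost with a pseudocount of 0.1 and with limma voom, and the PAPLN call without 0 mGy replicate 2 or 3 or 500 mGy replicate 1.

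With the replicate block 54 genes rose and 73 fell at 500 mGy at day 10. The rising genes included PAMR1 (3.17, SE 0.31), the growth factor-binding gene IGFBP5 (1.67, SE 0.27) and the potassium channel gene KCNK12 (1.86, SE 0.36). The falling genes included BHMT (-3.11, SE 0.41), ALDH1A1 (-2.77, SE 0.48), the T-box genes TBX2 (-2.25, SE 0.36) and TBX3 (-1.92, SE 0.26), the receptor gene FGFR3 (-2.12, SE 0.32), the crystallin gene CRYAB (-2.10, SE 0.42) and the proneural gene NEUROG1 (-2.15, SE 0.46). In simulated data that assumed the pairing, 10.99% of calls with the block were false for this comparison. Without the block the count was 48, 1 and 1 without 0 mGy replicates 1, 2 and 3, and 1, 21 and 5 without 500 mGy replicates 1, 2 and 3. The blocked count was 15 without day 10, 0 mGy, replicate 1, 7 without day 10, 0 mGy, replicate 3, and 10 without day 10, 500 mGy, replicate 3. It was 212, with 159 up and 53 down, without day 10, 500 mGy, replicate 2. It was 188, with 69 up and 119 down, without 500 mGy replicate 1, and 172, with 94 up and 78 down, without 0 mGy replicate 2. In replicates 2 and 3 only, 29 rose and 33 fell with the block, and 29 of these 62 were among the 127.

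Neuronal genes shifted down at 500 mGy at day 10 (camera adjusted p = 2.1e-13, and 0.062 with an estimated correlation). None of the 21 passed over all genes without the block and 10 passed downward when adjusted over the list alone. The value of HES6 was -1.43 (SE 0.41), which did not pass. BMP and TGF-beta targets shifted down (adjusted p = 2.2e-07, and 0.0636 with an estimated correlation), with SMAD7 at -0.90 (SE 0.26), which passed with the block (adjusted p = 0.0442). Neural crest, WNT target, extracellular matrix, DNA replication, mesoderm, and trophoblast and surface ectoderm genes shifted down (adjusted p = 2.18e-06, 5e-07, 1.82e-05, 2.5e-05, 0.0262 and 0.0262, and 0.25, 0.148, 0.0636, 0.476, 0.198 and 0.25 with an estimated correlation). The trophoblast and surface ectoderm call was lost with the block (adjusted p = 0.0562). Hypoxia and glycolysis genes shifted up (adjusted p = 0.00129, and 0.258 with an estimated correlation). With the block alone, pluripotency genes also passed upward, and mitosis, unfolded protein and NOTCH target genes downward (adjusted p = 0.0285, 0.0492, 0.0425 and 0.0473, and 0.4, 0.583, 0.622 and 0.4 with an estimated correlation). CDKN1A, MDM2, GDF15, BAX and FDXR were at 0.11, -0.12, 0.08, -0.36 and 0.16.

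**Figure D5:**
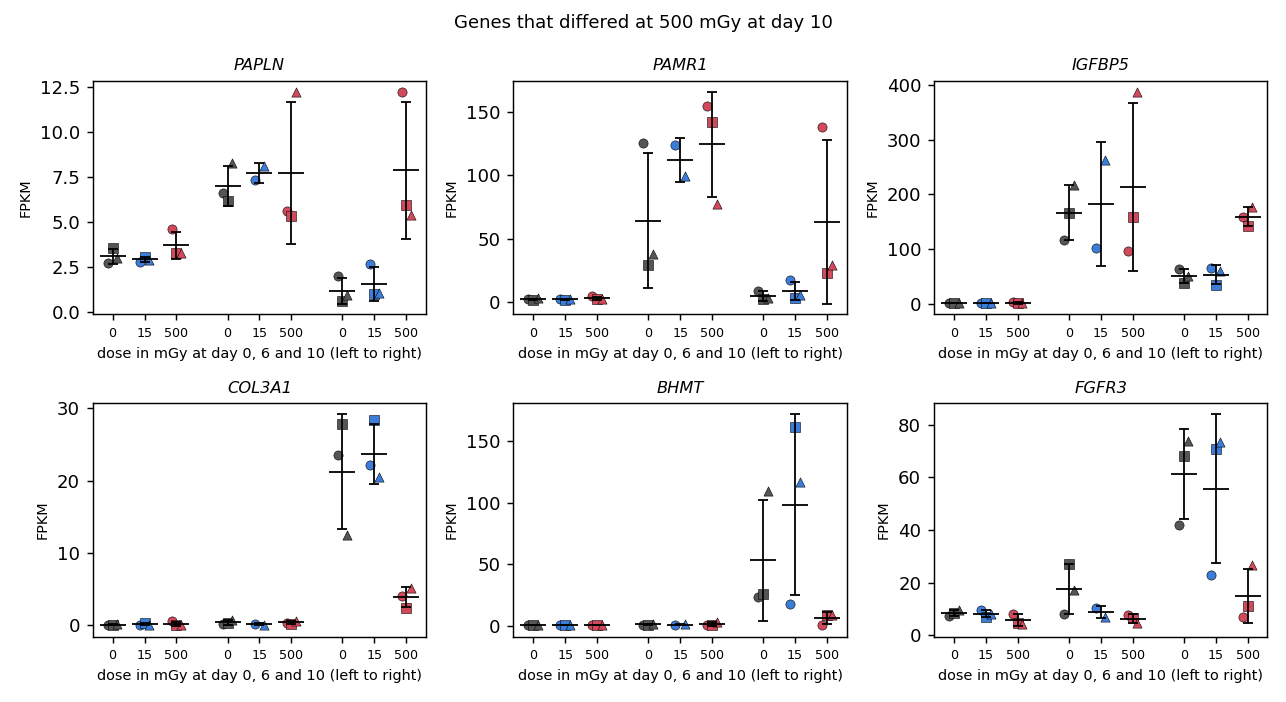
FPKM of 6 genes that passed the threshold at 500 mGy at day 10 with or without the replicate block, by dose at days 0, 6 and 10, with a point per library, shapes for replicate numbers, and bars for the mean and SD. COL3A1 had a mean of 3.86 FPKM after 500 mGy at day 10 and 21.2 FPKM at 0 mGy.

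After 15 mGy at day 10 no gene passed in limma, with or without the block or with limma voom, and 138 had an unadjusted p under 0.05. Without day 10, 15 mGy, replicate 1, 1 gene passed without the block. Neuronal genes shifted down (median -0.68, camera adjusted p = 1.05e-18, and 0.0153 with an estimated correlation), with 19 of 21 members negative. With the block the estimated correlation gave adjusted p = 0.216. Members with the smallest p were NEUROD1 (-1.12, SE 0.40), ELAVL4 (-0.97, SE 0.39), STMN4 (-0.68, SE 0.28) and ELAVL3 (-0.97, SE 0.40), none past the threshold. Neural crest genes shifted down (adjusted p = 1.88e-07, and 0.438 with an estimated correlation), a direction that reversed without day 10, 0 mGy, replicate 2 (adjusted p = 0.963). The same unirradiated libraries served the comparison with 500 mGy, so the downward shifts of these lists at the 2 doses are not independent. CDKN1A, MDM2, GDF15, BAX and FDXR were at 0.17, 0.10, 0.18, -0.11 and -0.02. Between the doses at day 10, 5 genes passed, named here after their values were seen. PAPLN (1.76, SE 0.30) and TINCR (1.77, SE 0.31) were higher at 500 than at 15 mGy, and PITX3 (-2.08, SE 0.36), COL3A1 (-2.37, SE 0.27) and RELN (-1.54, SE 0.26) were lower. With the block 51 genes were higher and 119 lower. The blocked count was 38 without 15 mGy replicate 2, 62 without 15 mGy replicate 3 and 60 without 500 mGy replicate 3, and without 500 mGy replicate 2 the balance turned to 106 higher and 62 lower. None of the 5 calls was made with a pseudocount of 0.1, the libraries of day 10 only or limma voom. Without the block the count was 166, 1 and 1 without 15 mGy replicates 1, 2 and 3, and 1, 18 and 20 without 500 mGy replicates 1, 2 and 3. BMP and TGF-beta targets were lower at 500 mGy (adjusted p = 2.33e-10, and 0.031 with an estimated correlation).

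Whether the response to a dose differed between days was tested as an interaction. No gene passed without the block for either dose. For 500 mGy 551 genes had an unadjusted p under 0.05 between days 6 and 0, and 557 between days 10 and 0. For 15 mGy the numbers were 71 and 84. With the block 3 genes passed for 500 mGy between days 10 and 0, and limma voom without the block called 0 in all 4 interactions. Without the block 1 gene passed for 500 mGy between days 6 and 0 without day 6, 500 mGy, replicate 1. Between days 10 and 0, 2 and 1 passed without day 10, 0 mGy, replicate 3 and day 10, 500 mGy, replicate 3. Of 23 lists, 10 passed for 500 mGy between days 6 and 0 and 8 between days 10 and 0, and 4 and 3 passed for 15 mGy. With an estimated correlation 1, 1, 0 and 0 passed. These were NOTCH targets, whose response to 500 mGy was lower at day 6 than at day 0 (camera adjusted p = 0.0104 with an estimated correlation, and 0.163 with the block too), and extracellular matrix and mesenchyme genes, whose response to 500 mGy was lower at day 10 than at day 0 (camera adjusted p = 0.0288, and 0.331 with the block too). The response of the p53 target list to 500 mGy was lower at day 6 and at day 10 than at day 0 (camera adjusted p = 5.03e-11 and 2.62e-05, and 0.137 and 0.391 with an estimated correlation). The apoptosis and interferon response lists passed in no comparison. The endoderm list and the hindbrain and HOX list had 3 measured members each and were not tested. Their medians from day 0 to day 6 were 0.79 and 0.75.

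The changes at 15 and 500 mGy were set against the same unirradiated libraries at each day. Across genes, which are not independent replicates, their correlation was 0.33 at day 0, 0.57 at day 6 and 0.37 at day 10, and simulated unchanged groups gave 0.50, 0.44 and 0.50. The covariance was 0.0115, 0.0470 and 0.0256, and simulated unchanged groups gave 0.0490, 0.0487 and 0.0489. The simulated libraries were drawn independently with the spread of the fit without the block. That spread includes any replicate difference that the doses of a day share, so these simulated values are no exact standard. At day 6, where 15 mGy lacks replicate 2, the correlation with the replicate block was 0.44 and the simulated one 0.45. The covariance there was 0.0351 and the simulated one 0.0255. At day 10, the day at which the replicate numbers are treated as pairing both doses with 0 mGy, the covariance with the replicate block was 0.0256 and the simulated one 0.0255. The 3 unirradiated libraries of a day are too few to be split, so part of the day 6 value may come from the shared controls. At days 0 and 10 shared controls alone gave about as large a covariance or a larger one in the simulations. The values of those days thus give no sign of a response common to both doses.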

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

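All tests in this part, of other groupings of the libraries and of explanations, were chosen after the result was seen, while the interactions were set before.

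The response of PAPLN to 500 mGy was higher at day 10 than at day 0 by 1.78 on the log2 scale, that of PAMR1 by 3.00 and that of the clone RP11-214O1.2 by 1.85, in the interaction fitted with the replicate block. These 3 genes were chosen after their values were seen, and none passed without the block. The response of NOTCH targets to 500 mGy was lower at day 6 than at day 0 (camera adjusted p = 0.0104 with an estimated correlation), and that of extracellular matrix and mesenchyme genes was lower at day 10 than at day 0 (adjusted p = 0.0288 with an estimated correlation). With the block these were 0.163 and 0.331.

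The p53 target genes were higher at 500 than at 0 mGy at day 0. Scaling of the libraries alone is argued against, since the median log2 change of the list was 0.42 with median-ratio scaling. The replicate 1 libraries alone are argued against too, since replicate pairs 1, 2 and 3 had medians of 0.74, 0.35 and 0.44. Pairs 2 and 3 may not be separate evidence, since their 500 mGy libraries were the closest of any group (chi-square per degree of freedom 4.685). These medians are without median-ratio scaling. In pair 1 the median-ratio factor was 0.675 at 0 mGy and 0.848 at 500 mGy, so part of 0.74 may be a shift of all genes. A response of these genes to 500 mGy in pluripotent cells is a candidate explanation, as a hypothesis. The list was set before the data were examined, while the checks here were chosen after and used the same data.

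Genes that rose from day 6 to day 10 in unirradiated cells were lower at 500 mGy at day 10. The 223 genes had a median of -0.61 against 0 mGy, and of -0.70 against 15 mGy, which shares no library with their choice and where all genes had a median of 0.01, so the shared unirradiated libraries are argued against. Replicate pairs 1, 2 and 3 had medians of -0.73, -0.79 and -0.48, against the replicate 1 libraries as the whole cause. The 19 genes that fell over the same days were higher at 500 than at 15 mGy (median 0.95, and 0 of 19 lower). They include PAPLN, PAMR1 and POU3F1, which had already passed upward at 500 mGy with the block, so this was partly known beforehand. Slower progression from day 6 to day 10 may account for both patterns, as a hypothesis. These values cannot tell it from a change in the kind of cell formed, neural or other, which was not tested and stays open.

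The replicate 1 libraries had the highest share of mitochondrially encoded reads in every group. Library depth is argued against, because in 6 of 9 groups replicate 1 did not have the fewest reads. Without these genes, 1 of the first 3 principal components still parted the replicate 1 libraries from all others, which bears on how the libraries separate and not on the share. What a replicate number stands for is not given in the sources used here, and no biological explanation was tested.

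Other groupings of the same 6 libraries make 10 splits, too few for a share under 0.05. From day 0 to day 6 the real split gave 5225 genes and the highest other 0, from day 0 to day 10 6107 and 0, and from day 6 to day 10 242 and 49, with 1 split as large in each. In these other splits each arm mixes libraries of both days. A large real difference then enters the spread of the fit and holds the count down, so the low counts tell little. Where the real count is 0 every split is as large by construction, so the number of such splits tells nothing. This holds for 15 minus 0 mGy at days 0 and 10 and 500 minus 0 mGy at day 6 (10 of 10 splits each), where the highest others were 867, 96 and 198. The split with 867 genes at day 0 put 0 mGy replicate 1 with 15 mGy replicates 1 and 2, and so points to a structure of the libraries. For 500 minus 0 mGy the values were 1 and 1 at day 0 (3 splits as large) and 2 and 4 at day 10 (2 splits). The split with 198 genes put 0 mGy replicate 1 with 500 mGy replicates 1 and 2. For 500 minus 15 mGy they were 2 and 20 at day 0 and 5 and 63 at day 10 (2 splits each). With the block, 4 splits part all pairs, which is also too few for a share under 0.05. These gave 13 and 0 for 500 minus 0 mGy at day 0, 127 and 6 at day 10, and 170 and 1 for 500 minus 15 mGy at day 10 (1 split as large in each). Here too a real difference would enter the spread of the other splits and hold their counts down, so the low counts tell little. At day 6 the count was 0 in all 4, which tells nothing. For the 3 interactions of groups with 3 libraries each the real counts were also 0, so that all 100 of the 100 splits drawn were as large by construction. The highest others were 54 for 15 mGy between days 10 and 0, and 22 and 6 for 500 mGy between days 6 and 0 and days 10 and 0. The interaction for 15 mGy between days 6 and 0 has a group of 2 libraries and was not split.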

How the results depend on the processing

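The fits of replicates 2 and 3 alone, limma voom and list tests without single libraries were chosen after the data were seen. With the replicate block, including comparisons whose numbers do not pair, the counts of changed genes were 548 for day 10 minus day 6, 1 for 15 minus 0 mGy, day 0, 13 for 500 minus 0 mGy, day 0, 127 for 500 minus 0 mGy, day 10, 7 for 500 minus 15 mGy, day 0, 170 for 500 minus 15 mGy, day 10 and 3 for 500 mGy effect, day 10 minus day 0. With the libraries of the same day, or unirradiated libraries, only they were 85 for day 10 minus day 6, 0 for 500 minus 0 mGy, day 0, 0 for 500 minus 0 mGy, day 10, 0 for 500 minus 15 mGy, day 0 and 0 for 500 minus 15 mGy, day 10. Without a filter they were 8 for 15 minus 0 mGy, day 0, 14 for 500 minus 0 mGy, day 0, 10 for 15 minus 0 mGy, day 6, 1 for 500 minus 0 mGy, day 6, 4 for 15 minus 0 mGy, day 10, 10 for 500 minus 0 mGy, day 10, 22 for 500 minus 15 mGy, day 0, 10 for 500 minus 15 mGy, day 6, 20 for 500 minus 15 mGy, day 10, 7 for 15 mGy effect, day 6 minus day 0 and 3 for 15 mGy effect, day 10 minus day 0. At a pseudocount of 0.1 they were 0 for 500 minus 0 mGy, day 0, 1 for 500 minus 0 mGy, day 10, 0 for 500 minus 15 mGy, day 0 and 0 for 500 minus 15 mGy, day 10. With median-ratio scaling they were 2 for 500 minus 0 mGy, day 0, 8 for 500 minus 15 mGy, day 0 and 1 for 500 mGy effect, day 10 minus day 0. With a log2 change of at least 1, which by construction keeps fewer genes, they were 2923 for day 6 minus day 0 and 3509 for day 10 minus day 0. In replicates 2 and 3 they were 6 for 500 minus 0 mGy, day 0, 4 for 500 minus 0 mGy, day 6, 99 for 500 minus 0 mGy, day 10, 159 for 500 minus 15 mGy, day 10 and 2 for 500 mGy effect, day 10 minus day 0. With limma voom on the recovered reads they were 0 for 500 minus 0 mGy, day 0, 1 for 500 minus 0 mGy, day 10, 0 for 500 minus 15 mGy, day 0 and 0 for 500 minus 15 mGy, day 10. With limma voom and the replicate block they were 640 for day 10 minus day 6, 4 for 500 minus 0 mGy, day 0, 1 for 500 minus 0 mGy, day 6, 151 for 500 minus 0 mGy, day 10, 0 for 500 minus 15 mGy, day 0, 179 for 500 minus 15 mGy, day 10 and 3 for 500 mGy effect, day 10 minus day 0. With the replicate block in replicates 2 and 3, run for 5 comparisons, they were 0 for 500 minus 0 mGy, day 0, 1 for 500 minus 0 mGy, day 6, 62 for 500 minus 0 mGy, day 10, 0 for 500 minus 15 mGy, day 0 and 136 for 500 minus 15 mGy, day 10. The gene past the threshold for 15 minus 0 mGy at day 0 with the block was RP11-44K6.2 (1.26, adjusted p = 0.0197), chosen after its values were seen. NOTCH targets for 500 minus 15 mGy at day 6, where the numbers do not pair, had adjusted p = 0.291 with the block and an estimated correlation. The oxidative stress list for day 10 minus day 0 had adjusted p = 0.0505 with the block. At days 0 and 6 the covariance of the changes at 15 and 500 mGy was 0.0115 and 0.0351 with the block, and simulated unchanged groups gave 0.0257 and 0.0255. Without 1 library at a time the counts ran from 4123 to 4940 for day 6 minus day 0, 5194 to 5800 for day 10 minus day 0, 49 to 279 for day 10 minus day 6, 0 to 1 for 15 minus 0 mGy, day 0, 0 to 8 for 500 minus 0 mGy, day 0, 0 to 0 for 15 minus 0 mGy, day 6, 0 to 30 for 500 minus 0 mGy, day 6, 0 to 1 for 15 minus 0 mGy, day 10, 1 to 48 for 500 minus 0 mGy, day 10, 0 to 11 for 500 minus 15 mGy, day 0, 0 to 0 for 500 minus 15 mGy, day 6, 1 to 166 for 500 minus 15 mGy, day 10, 0 to 0 for 15 mGy effect, day 6 minus day 0, 0 to 0 for 15 mGy effect, day 10 minus day 0, 0 to 1 for 500 mGy effect, day 6 minus day 0 and 0 to 2 for 500 mGy effect, day 10 minus day 0. All other counts under these settings stayed within 1.5 times. The cause of these changes was not tested, except where stated.

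With an estimated correlation the counts of gene lists past the threshold were 2 for day 6 minus day 0, 2 for day 10 minus day 0, 1 for day 10 minus day 6, 0 for 15 minus 0 mGy, day 0, 1 for 500 minus 0 mGy, day 0, 0 for 15 minus 0 mGy, day 6, 1 for 500 minus 0 mGy, day 6, 1 for 15 minus 0 mGy, day 10, 0 for 500 minus 0 mGy, day 10, 1 for 500 minus 15 mGy, day 0, 1 for 500 minus 15 mGy, day 6, 1 for 500 minus 15 mGy, day 10, 0 for 15 mGy effect, day 6 minus day 0, 0 for 15 mGy effect, day 10 minus day 0, 1 for 500 mGy effect, day 6 minus day 0 and 1 for 500 mGy effect, day 10 minus day 0. With median-ratio scaling they were 0 for 15 minus 0 mGy, day 0, 6 for 15 minus 0 mGy, day 10 and 7 for 15 mGy effect, day 6 minus day 0. In replicates 2 and 3 they were 2 for 15 minus 0 mGy, day 0, 7 for 500 minus 0 mGy, day 0, 11 for 15 minus 0 mGy, day 10, 3 for 500 minus 15 mGy, day 0, 9 for 500 minus 15 mGy, day 6, 8 for 15 mGy effect, day 6 minus day 0 and 5 for 15 mGy effect, day 10 minus day 0. Without 1 library at a time they ran from 6 to 7 for day 6 minus day 0, 5 to 8 for day 10 minus day 0, 8 to 10 for day 10 minus day 6, 0 to 3 for 15 minus 0 mGy, day 0, 4 to 7 for 500 minus 0 mGy, day 0, 6 to 11 for 15 minus 0 mGy, day 6, 8 to 13 for 500 minus 0 mGy, day 6, 1 to 5 for 15 minus 0 mGy, day 10, 8 to 10 for 500 minus 0 mGy, day 10, 4 to 6 for 500 minus 15 mGy, day 0, 2 to 6 for 500 minus 15 mGy, day 6, 8 to 10 for 500 minus 15 mGy, day 10, 3 to 9 for 15 mGy effect, day 6 minus day 0, 0 to 6 for 15 mGy effect, day 10 minus day 0, 7 to 11 for 500 mGy effect, day 6 minus day 0 and 6 to 14 for 500 mGy effect, day 10 minus day 0. The direction of 7 lists reversed without 1 library, with adjusted p from 1.56e-15 to 0.895 for mitochondrially encoded genes (15 minus 0 mGy, day 0), 1.51e-06 to 0.879 for immediate early genes (15 minus 0 mGy, day 6), 7.81e-13 to 0.963 for neural crest genes (15 minus 0 mGy, day 10), 2.36e-10 to 0.973 for mitochondrially encoded genes (500 minus 15 mGy, day 0), 5.83e-14 to 0.164 for mitochondrially encoded genes (15 mGy effect, day 6 minus day 0), 2.2e-07 to 0.705 for neural crest genes (15 mGy effect, day 10 minus day 0) and 2.78e-13 to 0.449 for mitochondrially encoded genes (15 mGy effect, day 10 minus day 0).

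Genes that had not passed changed sign without 1 library. For day 10 minus day 6 the log2 change ran from -0.46 to 0.22 for NES. For 15 minus 0 mGy, day 0 the log2 change ran from -0.51 to 0.23 for CDKN1A, -0.18 to 0.62 for MDM2, -0.35 to 0.37 for GDF15, -0.47 to 0.51 for BAX and -0.07 to 0.41 for FDXR. For 500 minus 0 mGy, day 0 the log2 change ran from -0.22 to 0.76 for BAX. For 15 minus 0 mGy, day 6 the log2 change ran from -0.23 to 0.11 for CDKN1A, -0.27 to 0.32 for MDM2, -0.15 to 0.17 for GDF15, -0.40 to 0.12 for BAX and -0.23 to 0.15 for FDXR. For 500 minus 0 mGy, day 6 the log2 change ran from -0.10 to 0.28 for FDXR. For 15 minus 0 mGy, day 10 the log2 change ran from -0.08 to 0.36 for CDKN1A, -0.09 to 0.25 for MDM2, -0.25 to 0.01 for BAX and -0.07 to 0.06 for FDXR. For 500 minus 0 mGy, day 10 the log2 change ran from -0.13 to 0.25 for CDKN1A, -0.30 to 0.15 for MDM2 and -0.23 to 0.25 for GDF15. BAX was at -0.07 with median-ratio scaling (15 minus 0 mGy, day 0), CDKN1A and BAX at 0.04 and 0.06 with the replicate block (15 minus 0 mGy, day 6) and FDXR at 0.00 with median-ratio scaling (15 minus 0 mGy, day 10). No named gene past the threshold reversed. The cause was not tested. At 6034935 reads, day 0, 15 mGy, replicate 2 limits what could be seen in genes of low level.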
